A study of Mus musculus with 12 samples.

How the data were processed

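The data are RNA sequencing libraries from mouse thymus. Per the labels, C57BL/6 mice received 10 μg of tamoxifen per g of body weight and were killed 7 days later, so that tdTomato marks cells that were labelled at a known time, and green fluorescent protein (GFP) reports Foxp3, the lineage transcription factor of regulatory T cells (Treg). Sorted CD4+ cells gave 4 groups of 3 libraries each: tdTomato+GFP+CD73+ cells (CD73+ newly generated Treg), tdTomato+GFP+CD73– cells (CD73– newly generated Treg), tdTomato+GFP–CD73– cells (newly generated conventional T cells, Tconv) and tdTomato–GFP+ cells (bulk tdTomato– Treg, not divided by CD73). RNA was extracted with TRIzol and libraries were made with the KAPA RNA HyperPrep kit, per the labels' protocols. Each title carries a letter, A, B or D, used here as the replicate name. The labels do not say that libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

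The submitters' processing notes name STAR, RSEM, limma and the mm10 build, with versions and options not given in the sources used here. The authors deposited log2 values per gene and library in 2 tables of 6 libraries, merged by gene ID. One table holds the CD73+ and CD73– newly generated Treg, and the other holds the tdTomato– Treg and Tconv. The deposited log2 values are CPM, counts scaled to a common library size, with an offset of 0.5 count, a unit read from the values themselves: in each library between 115 and 485 genes share the lowest value, which is the level of a gene with no count. The tables were filtered and normalised separately by the authors. Of 13207 genes, 12410 are in both tables, 250 are only in the first and 547 only in the second. The authors also deposited log2 fold changes, p-values and adjusted p-values for the comparison in each table.

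Because the tables were scaled separately, tests were made only within a table. Of 6 comparisons between groups planned before the data were examined, 4 cross the tables and were not run, among them CD73– newly generated Treg against Tconv, and so was a planned overlap of comparisons that share libraries. The 2 comparisons within a table are described. The comparison of tdTomato– Treg with Tconv had been planned as a secondary one.

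The lowest values give the depth behind each library, as the product of its size and the authors' scaling factor. This effective depth was 11000000 to 21400000 counts. A gene without counts in a library then has an upper limit of 3 counts, which is a log2 CPM between −2.61 and −1.65. This limit covers counting error only, since reads without molecular identifiers are not independent molecules. No group was found to hold the same library more than once.

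Linear models were fitted with limma 3.58.1 in R 4.3.3 to the deposited log2 values. All 12 libraries entered a single fit with 4 group means and no block, with an intensity trend in the empirical Bayes step. Genes were kept with a log2 CPM of at least 0 in at least 3 libraries. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, and an adjusted p under 0.05 is called past the threshold. Errors of levels are SD over 3 libraries and errors of log2 fold changes are standard errors (SE) of the fit.

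Before the data were examined, 19 gene lists were fixed from general knowledge: 11 of processes in the studied cells, 1 of handling and 7 of other cell types. They were tested with camera, with a preset correlation between genes of 0.01, over genes in both tables, and with an estimated correlation, and adjusted over the lists of a comparison; lists with fewer than 3 tested members were counted but not tested. Ribosomal protein, histone, mitochondrially encoded and Zfp zinc finger gene families were added after seeing the data. The rule for named genes was fixed before the data were examined. It takes the genes used for sorting, the 5 highest and 5 lowest fold changes among genes past the threshold whose groups do not overlap and whose mean is above the median, leaving out predicted genes, pseudogenes and receptor segments, and up to 2 members of each list per direction by p-value. For secondary comparisons it takes no highest and lowest fold changes, so those given for tdTomato– Treg against Tconv, and every gene said to be named after its values were seen, lie outside the rule. Values of some single list members are not reported here.

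Whether the letters pair libraries across groups was checked on 9942 genes, as the correlation of deviations from group means. Between CD73+ and CD73– Treg, libraries of the same letter correlated at 0.146 to 0.266, all above 0.1, so the letters were treated as pairing these libraries, and the fit with the letter as a replicate block is given where it changes a call or moves a count by more than 1.5 times.

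Alternatives planned before the data were examined were no filter on low values, a limit 1 log2 unit higher, a fold threshold, an adjusted p under 0.01, only the 2 groups compared, the replicate block, quantile normalisation within a table, robust limma with array weights, and each library left out. Chosen after seeing the data were vooma weights, leaving out the 4 libraries of letter D, lists tested in the 6 libraries of a table, and removal of a spline trend on transcript length and GC content in each library, with and without the block. The pseudocount alternative did not apply to values deposited on a log scale.

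Gene IDs were matched without version to GENCODE M21, whose genome is the mm10 build; 13206 of 13207 matched, and coordinates are taken from it. For 22 genes the symbol had been turned into a date and was restored by ID. The test was checked on simulated data drawn from the real means and spreads, with 200 genes changed. For CD73+ against CD73– Treg, over 11170 genes, 84.0% of genes changed by 1 log2 unit and 95.0% of those changed by 2 were recovered, and 5.79% of calls were false. For tdTomato– Treg against Tconv, over 11198 genes, the shares were 84.0%, 96.0% and 5.26%. Recovery of smaller changes was not measured. The median absolute log2 fold change of the genes past the threshold in the real data was 0.475 in the first comparison and 0.56 in the second.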

Results

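Gene expression was measured by RNA sequencing in CD4+ cells sorted from mouse thymus 7 days after tamoxifen, in 12 libraries of 4 groups with 3 libraries each. The effective depth was 11000000 to 21400000 counts per library. Reads assigned to a single gene, Lars2, made up 16.1% to 32.4% of the summed CPM of a library, and no other gene held more than 0.792%. Lars2 encodes a mitochondrial leucyl-tRNA synthetase. Its share was 25.8% ± 2.95 (SD, n = 3) in CD73– newly generated Treg, 29.6% ± 0.952 in CD73+ newly generated Treg, 23.4% ± 6.32 in Tconv and 31.5% ± 0.827 in tdTomato– Treg. The difference in its log2 CPM between CD73+ and CD73– Treg was not past the threshold (log2 fold change 0.27, SE 0.21, adjusted p = 0.54), and its log2 CPM was higher in tdTomato– Treg than in Tconv (0.63, SE 0.22, adjusted p = 0.024). Whether the reads assigned to Lars2 come from its messenger RNA was not tested, so these values may not be a level of expression. Within groups, Spearman correlations across genes were 0.992 to 0.996. They were 0.988 to 0.993 between CD73+ and CD73– Treg and 0.945 to 0.949 between tdTomato– Treg and Tconv. Genes are not independent replicates in these correlations.

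Foxp3 and Nt5e followed the gates that used them. Foxp3 (ENSMUSG00000039521.13, chromosome X, 7573644 to 7595245) had a log2 CPM of 9.19 ± 0.07 (SD, n = 3) in CD73+ Treg and 9.16 ± 0.05 in CD73– Treg, a difference within its error (log2 fold change 0.03, SE 0.25, adjusted p = 0.96). In the second table it was 9.11 ± 0.05 in tdTomato– Treg and 0.18 ± 0.85 in Tconv. Nt5e, which encodes CD73 (ENSMUSG00000032420.8, chromosome 9, 88327197 to 88372092), was 7.29 ± 0.14 in CD73+ Treg and 5.54 ± 0.17 in CD73– Treg (log2 fold change 1.75, SE 0.09, adjusted p = 1.2e-08), and 8.21 ± 0.03 in tdTomato– Treg against 3.88 ± 0.17 in Tconv (log2 fold change 4.33, SE 0.09). Cd4 was not past the threshold between the newly generated Treg (log2 fold change −0.13, SE 0.06, adjusted p = 0.27) and was lower in tdTomato– Treg than in Tconv (log2 fold change −0.84, SE 0.06, adjusted p = 2.1e-09). Foxp3, and Nt5e between CD73+ and CD73– Treg, check the sort and are no finding. The gates do not set the level of Nt5e in tdTomato– Treg, which were not divided by CD73. Tconv were sorted as CD73–, so the difference in Nt5e between tdTomato– Treg and Tconv was partly set by the gates. The difference in Cd4, between groups that were all sorted as CD4+, was not set by them.

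**Figure D1:**
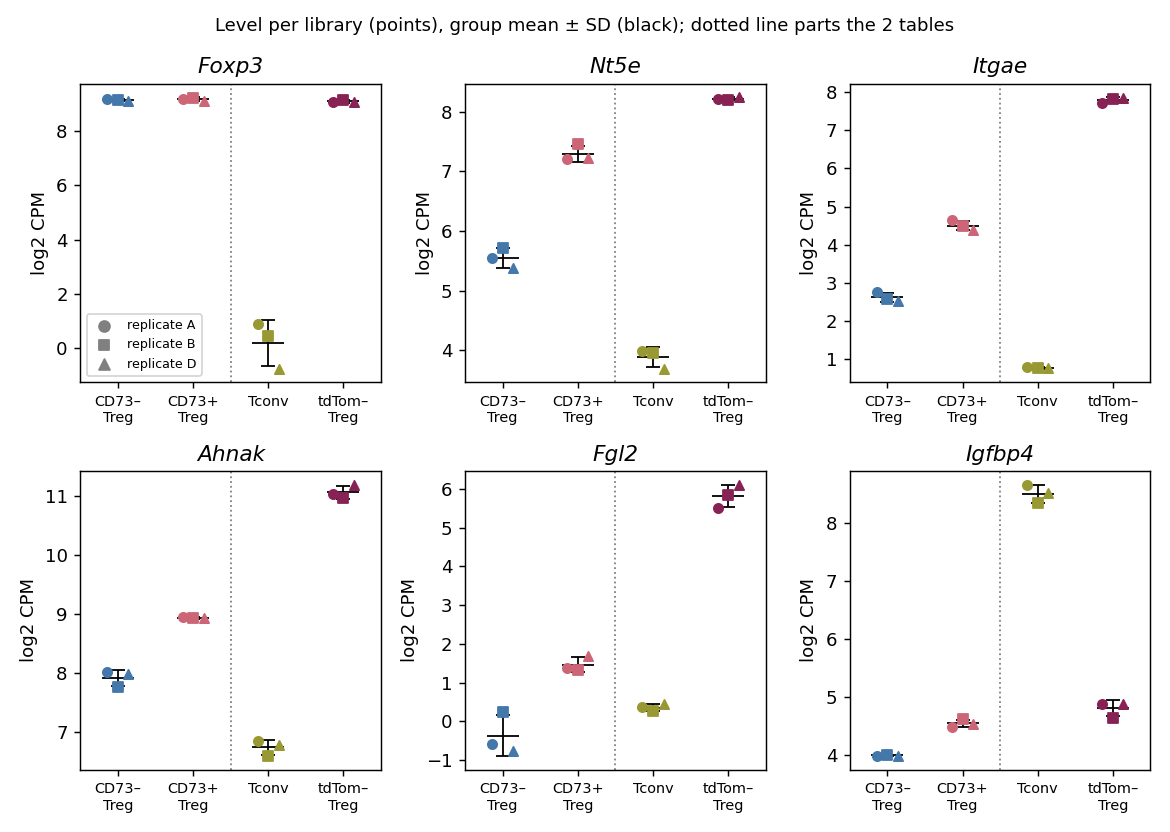
Log2 CPM of 6 genes (vertical axes) in the 4 groups (horizontal axes), with 1 point per library, its shape giving the replicate letter, and black bars for the mean ± SD of 3 libraries. Itgae and Ahnak lie higher in all 3 CD73+ than in all 3 CD73– Treg libraries, and the dotted line parts the tables, which were normalised separately, so that levels are not tested across it.

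The first comparison asked how newly generated thymic Treg that carry CD73 differ in expression from those that do not. Genes of activated, tissue-type (effector) Treg were higher in the CD73+ cells: of 28 measured members of that list 10 rose and none fell (17 rose when adjusted over the list alone). Without the 4 libraries of letter D, Ahnak, Itgae and Entpd1 rose, 3 of the 25 members tested there. Without CD73+ replicate A, 6 of 28 rose. Itgae, which encodes the integrin chain CD103, had a log2 CPM of 4.50 ± 0.13 (SD, n = 3) against 2.62 ± 0.12 (log2 fold change 1.88, SE 0.11, adjusted p = 1.6e-08). Ahnak (ENSMUSG00000069833.13, chromosome 19, 8989284 to 9076914), a large scaffold protein, was 8.93 ± 0.02 against 7.92 ± 0.14 (log2 fold change 1.02, SE 0.07, adjusted p = 5.3e-07). The other 8 members past the threshold, named after their values were seen, were Il1rl1, Fgl2, Ccr8, S100a6, Tigit, Cxcr3, Entpd1 and S100a4. Ccr8, a chemokine receptor, rose from 3.74 ± 0.10 to 4.36 ± 0.01, and Entpd1, which encodes the ectonucleotidase CD39, from 2.05 ± 0.18 to 3.22 ± 0.25. Tigit, an inhibitory receptor, and Il1rl1, the interleukin-33 receptor chain, were low in both groups, at 0.80 ± 0.11 against −2.58 ± 1.94 and at −0.27 ± 0.22 against −4.27 ± 0.66, where the CD73– values rest on few counts. In CD73– Treg the levels of Il1rl1, S100a6, Tigit and Cxcr3 lie near or under the limit that 3 counts allow. Calls ended when 1 library was left out for Cxcr3 (CD73– replicate A or D or CD73+ replicate A or D, adjusted p = 0.0533 to 0.0592), Entpd1 (CD73– replicate A or D or CD73+ replicate A or B, 0.0533 to 0.121), S100a4 (CD73– replicate A or B or CD73+ replicate A or B, 0.0542 to 0.153, and 0.0881 with quantile normalisation) and Tigit (CD73+ replicate A, 0.0585). The list passed the test (camera adjusted p = 8.9e-17, and adjusted p = 0.0031 with an estimated correlation).

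The general Treg signature moved the same way, with 6 of 20 measured members higher and none lower (11 adjusted over the list alone; camera adjusted p = 2.4e-11, and adjusted p = 0.023 with an estimated correlation). Capg, an actin-capping protein, rose by 0.64 on the log2 scale (SE 0.08, adjusted p = 5.6e-04), and Nrp1, Lrrc32, Cd83 and Izumo1r, named after their values were seen, were also past the threshold, besides Itgae, which is on both lists. Without any 1 of CD73– replicate D and CD73+ replicates A and B only 3 members of the signature rose, Itgae, Capg and Nrp1, as Lrrc32 lost its call (adjusted p = 0.0731 to 0.0897). Cd83 lost it without any library but CD73– replicate B (0.0689 to 0.211) and with quantile normalisation (0.0514), and Izumo1r without any but CD73– replicate A (0.0602 to 0.198). Without the 4 libraries of letter D, 4 members rose, namely Itgae, Capg, Nrp1 and Lrrc32. Of 20 genes induced by T cell receptor signals, 2 rose and none fell, namely Pdcd1, an inhibitory receptor (log2 fold change 0.52, SE 0.10, adjusted p = 0.0096), and Irf4, a transcription factor (0.35, SE 0.08, adjusted p = 0.027). Adjusted over the list alone, 5 rose. Without the 4 libraries of letter D neither Pdcd1 nor Irf4 was past the threshold. That list passed with the preset correlation (camera adjusted p = 0.0051) and not with an estimated one (adjusted p = 0.14), nor without CD73– replicate B (adjusted p = 0.106) or CD73+ replicate D (adjusted p = 0.0587). Irf4 was not past the threshold without CD73– replicate A or D or CD73+ replicate A or B (adjusted p = 0.0553, 0.118, 0.0656 and 0.140). Of 15 targets of STAT5, the transcription factor downstream of interleukin-2, Pim1 rose (log2 fold change 0.57, SE 0.08, adjusted p = 0.0012) and Lta fell (−0.38, SE 0.09, adjusted p = 0.037), and the list did not pass (camera adjusted p = 0.34). Adjusted over the list alone, 3 rose and 1 fell. Socs3 rose too without CD73– replicate B (adjusted p = 0.0135). Lta lost its call without any 1 of CD73– replicates A and D and CD73+ replicates A, B and D (adjusted p = 0.106, 0.138, 0.0656, 0.153 and 0.0779). It lost it without the 4 libraries of letter D too (adjusted p = 0.297).

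Genes of immature thymocytes were lower as a list (camera adjusted p = 0.0017; adjusted p = 0.14 with an estimated correlation), with 2 of 17 members down and 1 up (4 down and 1 up adjusted over the list alone). Themis, a signalling protein of thymocyte selection, fell by 0.38 on the log2 scale (SE 0.06, adjusted p = 0.0025), and Satb1, a chromatin organiser, fell by 0.32 (SE 0.05, adjusted p = 0.0037), while Ccr4, a chemokine receptor, rose by 1.05 (SE 0.16, adjusted p = 0.0017). Without the 4 libraries of letter D only Satb1 of these 3 was past the threshold (adjusted p = 0.054 for Themis and 0.082 for Ccr4). With the replicate block, Ccr9 and Rag1 fell too. Of 13 genes of naive conventional T cells, 1 rose and 1 fell (1 and 5 adjusted over the list alone). Igfbp4 rose (log2 fold change 0.55, SE 0.09, adjusted p = 0.0023) and Satb1 fell. Without letter D Igfbp4 lost its call (adjusted p = 0.082). The list did not pass (camera adjusted p = 0.085) and did so with the block (adjusted p = 0.024), where Pde3b and Lef1 fell as well, and without CD73+ replicate A (adjusted p = 0.0429). Over its alternatives the adjusted p of this list was 0.0242 to 0.486. Pde3b also fell without CD73– replicate B or CD73+ replicate D (adjusted p = 0.0381 and 0.0285). Of 20 maturation and egress genes, Il7r, the interleukin-7 receptor chain, rose (0.73, SE 0.10, adjusted p = 0.0012), and Ms4a4b and S1pr1 fell with the block. The list did not pass (camera adjusted p = 0.66), with 1 up and 1 down adjusted over the list alone. Of 20 cell cycle genes, Tk1, a nucleotide salvage kinase, rose (0.78, SE 0.15, adjusted p = 0.013), and with the block Mcm2, Mcm5 and Top2a rose as well. Adjusted over the list alone, 2 rose. The list passed (camera adjusted p = 0.0015) but not with an estimated correlation (adjusted p = 0.49) or without CD73+ replicate B (adjusted p = 0.0586), where Tk1 lost its call too (adjusted p = 0.0714). Tk1 also lost it without letter D (adjusted p = 0.113). Without CD73– replicate B, Mcm2, Mki67 and Top2a rose besides Tk1 (adjusted p = 0.0068, 0.0104 and 0.0052).

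No member of the lists of NF-kB targets (16 measured), apoptosis regulators (14), interferon response (21) and immediate early and heat shock genes (17) was past the threshold, and none of those lists passed (camera adjusted p = 0.61, 0.26, 0.057 and 0.66). Adjusted over the list alone, none of their members passed either. With the block, the interferon response list was lower (camera adjusted p = 0.020), with Oasl2 and Zbp1 down, and Ier2 of the immediate early genes was up. The interferon list was also lower without CD73– replicate A or D or CD73+ replicate B (adjusted p = 0.0049, 0.0306 and 0.0047) or without the 4 libraries of letter D (adjusted p = 0.034). Over its alternatives its adjusted p was 0.00472 to 0.706. Without CD73– replicate D the immediate early and heat shock list was higher (adjusted p = 0.0304). With all libraries and an estimated correlation its camera adjusted p was 0.92. The mean log2 CPM of 5 AP-1 genes was 6.69, 7.52 and 8.25 in CD73– replicates B, A and D and 7.06, 7.71 and 8.38 in the CD73+ replicates of the same letters. It was higher in all 3 pairs, a difference that was not tested.

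Markers of other cells changed in few cases. Of 10 genes of CD8 and double-positive thymocytes, Nkg7, a granule protein of cytotoxic cells, rose (log2 fold change 1.68, SE 0.26, adjusted p = 0.0024) and Aqp11 fell from 2.46 ± 0.28 to 1.46 ± 0.07 (adjusted p = 0.032), and 2 rose and 4 fell adjusted over the list alone. The list did not pass (camera adjusted p = 0.22, and adjusted p = 0.71 with an estimated correlation) and was lower without CD73– replicate D (adjusted p = 0.0066 with the preset correlation). Arpp21 fell there (adjusted p = 0.0417). Without the 4 libraries of letter D the list was also lower (adjusted p = 0.0077). No member was past the threshold there (adjusted p = 0.067 for Nkg7 and 0.087 for Aqp11). With the block Runx3 rose and Rag1 fell, and Runx3 also rose without CD73– replicate B or CD73+ replicate A (adjusted p = 0.0226 and 0.0183). Aqp11 was not past the threshold without CD73– replicate A or B or without any 1 of CD73+ replicates A, B and D (adjusted p = 0.0731, 0.0805, 0.0857, 0.121 and 0.0673). Of 4 measured genes of innate-like T and NK cells, Zbtb16, a transcription factor of innate-like T cells, was 1.07 ± 0.32 against −2.80 ± 1.91 (adjusted p = 0.0041). The CD73– level lies under the limit that 3 counts allow. Zbtb16 was not past the threshold without letter D (adjusted p = 0.105). That list did not pass (camera adjusted p = 0.61), and its median log2 fold change was −0.17 while its mean was 0.70. No member was past the threshold of 4 B cell, 12 myeloid and dendritic, 3 thymic epithelial, 5 erythroid and 1 stromal or endothelial markers (camera adjusted p = 0.996, 0.66, 0.48 and 0.76 for the first 4 lists, the last not being tested), nor adjusted over the list alone. With the block Cst3 of the myeloid list rose, and without CD73– replicate D that list was higher (adjusted p = 0.0306). With all libraries and an estimated correlation the camera adjusted p of the myeloid list was 0.92.

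Over all genes, 276 of 11170 were past the threshold, 199 higher and 77 lower in CD73+ Treg. Besides Nt5e and Ahnak, the highest fold changes by the rule were those of Tiam1, an activator of Rac (log2 fold change 0.81, SE 0.07; chromosome 16, 89787111 to 90143769), Itgb8, an integrin chain (0.81, SE 0.20; chromosome 12, 119158022 to 119238802), and the histone gene Hist1h4m (0.75, SE 0.10; chromosome 13, 21811746 to 21812147), whose reads cannot be told with certainty from those of its near-identical copies. The lowest were those of Prrg1 (−0.46, SE 0.10), Als2cl (−0.46, SE 0.10), Zfp607a (−0.41, SE 0.09), Rasgrp2, a Rap activator (−0.41, SE 0.08), and the integrin chain Itgb3 (−0.41, SE 0.06). Leaving out 1 library ended the call of Itgb8 for any library but CD73– replicate B (adjusted p = 0.0717 to 0.178), of Prrg1 for any but CD73+ replicate B (at least 0.0502), and of Als2cl without CD73– replicate A or D or CD73+ replicate A or B (0.0656 to 0.146). It ended that of Zfp607a without CD73– replicate A or D or CD73+ replicate A (0.0551 to 0.0910) and that of Rasgrp2 without CD73– replicate D or CD73+ replicate A or B (0.0684 to 0.0990). Without the 4 libraries of letter D the calls of Prrg1, Als2cl and Zfp607a ended (adjusted p = 0.156, 0.113 and 0.168). Of all tested genes 18.2% had groups that did not overlap, where chance gives 10%. By the authors' deposited table, 151 genes pass the same threshold, 116 higher and 35 lower, of which 131 are among the 276. With the replicate block 658 genes were past the threshold, 389 higher and 269 lower, while only the 2 groups compared gave 151, and the count was 46 without the 4 libraries of letter D. Leaving out 1 library gave 161 without CD73– replicate A, 135 without CD73– replicate D, 105 without CD73+ replicate A and 101 without CD73+ replicate B.

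The second comparison set bulk tdTomato– Treg, cells that did not carry the time stamp, against newly generated Tconv. The groups differed in lineage, in labelling and in gating on CD73, since Tconv were sorted as CD73– and tdTomato– Treg were not divided by CD73. Of all tested genes 52.1% were past the threshold here, a share to be set beside the counts of list members in this comparison. All 20 members of the Treg signature rose, adjusted over all genes and adjusted over the list alone (camera adjusted p = 8.1e-26, and adjusted p = 0.0020 with an estimated correlation). The rise of Foxp3 among them was set by the gates, and the list was not tested without it. Lrrc32, which encodes the TGF-beta docking receptor GARP (chromosome 7, 98489283 to 98502181), had a log2 CPM of 8.47 ± 0.11 (SD, n = 3) against 1.20 ± 0.16 (log2 fold change 7.26, SE 0.09, adjusted p = 1.7e-18). Il2rb, an interleukin-2 receptor chain, was 9.45 ± 0.07 against 5.44 ± 0.10 (log2 fold change 4.01, SE 0.06, adjusted p = 7.9e-18). Of 30 effector Treg genes 28 rose, 1 fell and 1 did not pass, the counts adjusted over the list alone being the same (camera adjusted p = 3.8e-14, and adjusted p = 0.0020 with an estimated correlation). Itgae was 7.79 ± 0.07 against 0.78 ± 0.02 and Ahnak 11.06 ± 0.11 against 6.74 ± 0.13, while Id2, a transcriptional regulator, fell by 1.49 on the log2 scale (SE 0.11, adjusted p = 9.4e-09). Cxcr6 did not pass, and fell with quantile normalisation (adjusted p = 0.0264). Klrg1 and Il10, named after their values were seen, had no counts in the Tconv libraries and were at least 25.1-fold and 20.1-fold higher in tdTomato– Treg, with 3 counts per library as the limit. Klrg1, Il10, Il1rl1 and Gzmb passed the filter only through the 3 tdTomato– Treg libraries, the group where they were higher. Leaving out any 1 of these libraries therefore removed the genes by the filter, whatever their level in the others. Without letter D the filter removed Cxcr3 besides.

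Of 15 STAT5 targets 12 rose and 2, Ccnd2 and Bcl2, fell (camera adjusted p = 3.4e-09, and adjusted p = 0.0020 with an estimated correlation). That list shares Foxp3, Il2ra, Il2rb and Socs2 with the Treg signature. The counts adjusted over the list alone were also 12 and 2 here, 13 and 3 for the genes induced by T cell receptor signals and 2 and 11 for the naive conventional T cell genes. Of 16 NF-kB targets 15 rose and none fell (camera adjusted p = 4.8e-10, and adjusted p = 0.0072 with an estimated correlation), with Nfkb2 up by 1.42 on the log2 scale (SE 0.07) and Traf1 by 1.51 (SE 0.08), and adjusted over the list alone all 16 rose. Of 20 genes induced by T cell receptor signals 13 rose, among them Tnfrsf9 (log2 fold change 2.18, SE 0.06) and Rel (1.43, SE 0.05), and Ikzf1, Egr1 and Bcl2l11 fell (camera adjusted p = 1.0e-04, and adjusted p = 0.031 with an estimated correlation). Naive conventional T cell genes fell in 11 of 13 cases, Cd226 and Il4ra rising (camera adjusted p = 1.2e-06, and adjusted p = 0.025 with an estimated correlation). Igfbp4, an insulin-like growth factor binding protein, fell by 3.71 on the log2 scale (SE 0.09, adjusted p = 1.55e-15), and Satb1 fell by 1.69 (SE 0.05). Bcl2 (log2 fold change −0.13, SE 0.05) lost its call without Tconv replicate A or any 1 of tdTomato– Treg replicates A, B and D (adjusted p = 0.241, 0.0562, 0.122 and 0.103), and with quantile normalisation (adjusted p = 0.102). Bcl2l11 (−0.20, SE 0.07) lost it without Tconv replicate A or D or tdTomato– Treg replicate B (adjusted p = 0.0832, 0.0978 and 0.145). Both genes lost it without letter D (adjusted p = 0.094 and 0.075), where the filter removed Dapl1 of the naive list.

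Cell cycle genes were lower in tdTomato– Treg, with 18 of 20 down and Tk1 up (19 down adjusted over the list alone; camera adjusted p = 5.4e-06, and adjusted p = 0.20 with an estimated correlation). Stmn1, a microtubule regulator, fell by 2.40 on the log2 scale (SE 0.11), and Top2a, a topoisomerase of dividing cells, fell by 1.98 (SE 0.21). Of 17 immature thymocyte genes 9 fell, among them Satb1 and Sox4 (log2 fold change −1.67, SE 0.06), and Slamf1, Myb, Cd69, Ccr4 and Rag1 rose (camera adjusted p = 0.033, and adjusted p = 0.20 with an estimated correlation). Of 20 maturation and egress genes 13 rose, with Itga4, an integrin chain, up by 0.81 on the log2 scale (SE 0.05), and Il7r, Ms4a4b, Dgka and Ccr7 fell, Ccr7 not without Tconv replicate A or without letter D (adjusted p = 0.0682 and 0.147; camera adjusted p = 0.0032, and adjusted p = 0.081 with an estimated correlation). Of 14 apoptosis regulators 7 rose, with Bcl2l1, a survival factor, up by 1.20 (SE 0.08) and Pmaip1, which promotes cell death, up by 3.42 (SE 0.24), and Bcl2l11 and Bcl2 fell (camera adjusted p = 0.033, and adjusted p = 0.081 with an estimated correlation). Adjusted over the list alone, the counts up and down were again 5 and 9 for the immature thymocyte, 13 and 4 for the maturation and egress and 7 and 2 for the apoptosis genes. Without 1 library, Bcl2 was not past the threshold in the cases of Tconv replicate A and tdTomato– Treg replicates A, B and D (adjusted p = 0.0562 to 0.241), nor Bcl2l11 in those of Tconv replicates A and D and tdTomato– Treg replicate B (0.0832 to 0.145). Neither was without letter D (0.094 and 0.075). Of 21 interferon response genes 6 rose and 9 fell (7 and 9 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.34).

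**Figure D2:**
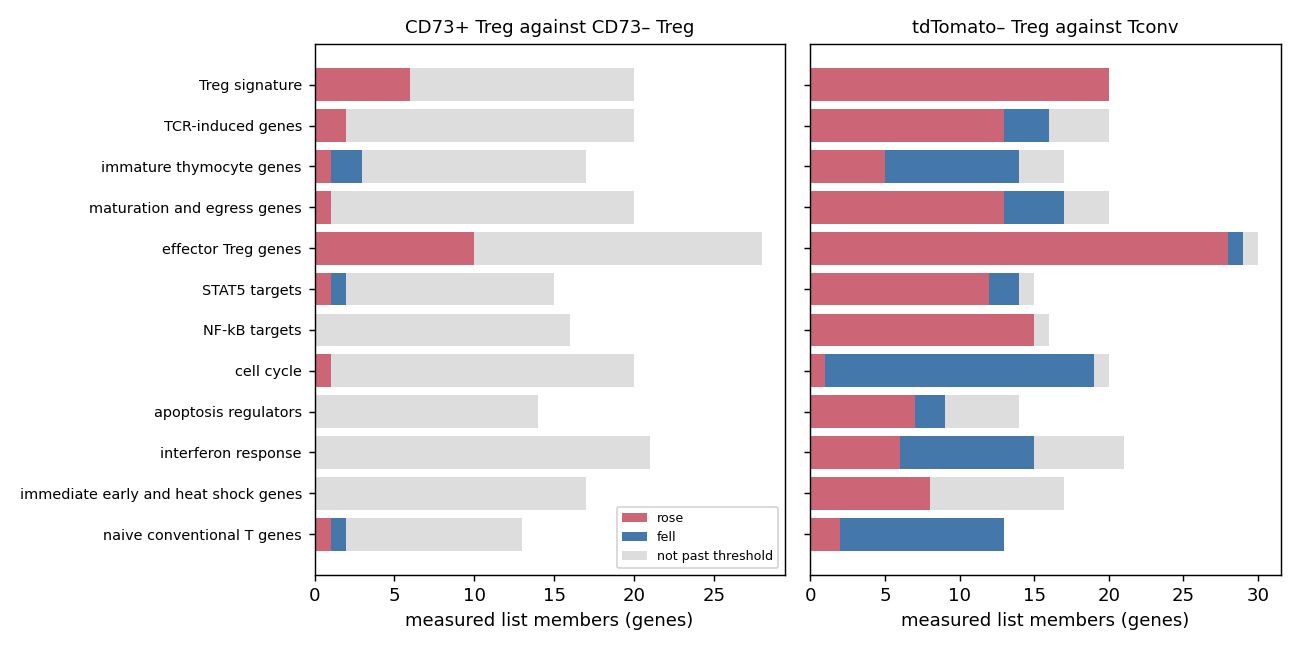
Number of measured members (horizontal axes) of 12 gene lists (vertical axis) that rose, fell or were not past an adjusted p of 0.05, in the 2 comparisons. In CD73+ against CD73– Treg the effector Treg list holds 10 members that rose and none that fell, and in tdTomato– Treg against Tconv the cell cycle list holds 18 that fell and 1 that rose.

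In the immediate early and heat shock list 8 of 17 members rose and none fell (also 8 adjusted over the list alone). Over all tested genes 52.1% were past the threshold, in either direction. Without Tconv replicate A, 6 rose and Hspa8 and Hsp90aa1 fell (adjusted p = 0.0083 and 0.0467). Without Tconv replicate B or tdTomato– Treg replicate D, 5 rose. The list did not pass (camera adjusted p = 0.10), and was higher without Tconv replicate D or tdTomato– Treg replicate B (adjusted p = 0.0099 and 0.0325). It was also higher without the 4 libraries of letter D (adjusted p = 0.012). With all libraries and an estimated correlation its camera adjusted p was 0.75. Jun was 8.95 ± 0.36 against 6.71 ± 0.93 (log2 fold change 2.24, SE 0.38, adjusted p = 1.2e-04) and Btg2 rose by 0.41 (SE 0.06), whereas the heat shock genes Hspa1a (−0.39, SE 0.86) and Hspa1b (−0.53, SE 0.74) were not past the threshold (adjusted p = 0.73 and 0.58). With the replicate block 11 members of the list rose and 4 fell, Hspa1a and Hspa1b among them (adjusted p = 0.0035 and 1.1e-04). The same-letter correlations here were 0.0536 to 0.117, so not all were above 0.1. The AP-1 and heat shock genes also varied between replicates: the mean log2 CPM of 5 AP-1 genes was 5.98, 6.66 and 7.71 in Tconv replicates B, A and D and 8.10, 8.38 and 8.97 in the tdTomato– Treg replicates of the same letters. The mean of 6 heat shock genes was 7.04, 7.25 and 8.145 in those Tconv replicates and 6.87, 7.08 and 7.875 in the tdTomato– Treg replicates. It was lower in tdTomato– Treg for each letter, a difference that was not tested.

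Markers of other cells were also unequal, in a comparison where 52.1% of all tested genes were past the threshold. Where about that share of a list was called, the number called does not by itself set the list apart from the genes at large. The share pools both directions and is no test of a list. Of 12 myeloid and dendritic markers 8 rose, with the protease Ctss up by 1.04 on the log2 scale (SE 0.07) and the class II chaperone Cd74 by 1.10 (SE 0.15), and Itgam fell (9 and 1 adjusted over the list alone). The markers that rose were 5 without Tconv replicate B, 3 without tdTomato– Treg replicate A and 3 with quantile normalisation. That list passed (camera adjusted p = 0.033) but not with an estimated correlation (adjusted p = 0.47) or without tdTomato– Treg replicate A (adjusted p = 0.0719). Of 4 B cell markers Cd79b, Bank1 and Ly6d rose (camera adjusted p = 0.12). Ly6d was not past the threshold without Tconv replicate A or B or tdTomato– Treg replicate A or B (adjusted p = 0.0828 to 0.145), nor with quantile normalisation (adjusted p = 0.614). Of 10 markers of CD8 and double-positive thymocytes 4 rose, among them Nkg7, Arpp21 and Rag1, and Cd8b1 and Runx3 fell (camera adjusted p = 0.73). With quantile normalisation 4 rose and 4 fell, Aqp11 and Cd8a falling too (adjusted p = 0.0090 and 0.013). Aqp11 also fell without tdTomato– Treg replicate A (adjusted p = 0.0440). Of 5 innate-like T and NK markers Eomes and Il23r rose and Zbtb16 and Sox13 fell (camera adjusted p = 0.87). Sox13 did not fall past the threshold without letter D (adjusted p = 0.080). Of 3 thymic epithelial markers Epcam rose and Ccl25 fell (camera adjusted p = 0.89). Ccl25 lost its call without Tconv replicate A or B or tdTomato– Treg replicate A or B (adjusted p = 0.126, 0.148, 0.187 and 0.0937). Of 5 erythroid markers Hba-a2 and Hbb-bs rose (3 adjusted over the list alone; camera adjusted p = 0.19). Hbb-bs was not past the threshold without tdTomato– Treg replicate B (adjusted p = 0.0561), and Hba-a1 and Hbb-bt rose too without Tconv replicate A or tdTomato– Treg replicate D. Of 2 stromal or endothelial markers, too few to test, Col1a2 rose, being at least 7.67-fold higher over Tconv libraries without counts. Col1a2 and Il23r passed the filter only through the 3 tdTomato– Treg libraries, so the filter removed them without any 1 of these or without letter D. No stromal marker and, of the innate-like list, only Eomes rose there. For the other lists of this paragraph the counts adjusted over the list alone were those over all genes.

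Over all genes, 5833 of 11198 were past the threshold, 2956 higher and 2877 lower in tdTomato– Treg, with 1724 changed at least by 1 log2 unit, of which 1252 were higher and 472 lower. The highest and lowest fold changes here, taken outside the rule, were ranked only among genes whose mean is above the median. After Foxp3, Lrrc32 and Itgb8 (log2 fold change 6.79, SE 0.20), the highest among these were those of Coro2a, a coronin (6.31, SE 0.12; chromosome 4, 46536937 to 46602202), and Il2ra, the interleukin-2 receptor chain CD25 (5.70, SE 0.08; chromosome 2, 11642807 to 11693193). Outside that limit Klrg1 (7.46), Il1rl1 (7.31) and Il10 (7.14), for example, had larger fitted log2 fold changes than Itgb8. Klrg1 and Il10 had no counts in the Tconv libraries, and the Tconv level of Il1rl1 rests on few counts. Whether these genes rose more than Itgb8 therefore cannot be told. Within the same limit the lowest after Igfbp4 were those of Pde3b, a phosphodiesterase (−3.32, SE 0.15), Itgb3 (−2.79, SE 0.06), Ccr9, a chemokine receptor of thymocytes (−2.68, SE 0.14), and Tgfbr3, a TGF-beta co-receptor (−2.64, SE 0.10). Outside it, Nrgn (−4.11) and Zbtb16 (−3.47), for example, fell more than Pde3b. By the authors' deposited table, 6558 genes pass, 3462 higher and 3096 lower, and 5735 of them are among the 5833.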

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

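Vooma weights, the fits without letter D, the lists in the 6 libraries of a table and the removal of the trend on length and GC content were chosen after seeing the data. Between CD73+ and CD73– Treg, the 276 genes past the threshold became 61 with a log2 fold change of at least 1, 71 at an adjusted p under 0.01, 151 with only the 2 groups compared, 658 with the replicate block, 46 without the 4 libraries of letter D and 732 with the trend on length and GC content removed together with the replicate block, of which 335 were higher and 397 lower; fewer genes can pass the stricter thresholds by construction, and otherwise the cause was not tested. Leaving out 1 library gave 101 to 369 genes. The trend removed without the block gave 277 genes, of which 162 were higher and 115 lower, against 199 and 77 before; 214 of the 276 were among them. All 276 were called again with the block alone, and 262 of them with the block and the trend removed. Between tdTomato– Treg and Tconv, 5833 genes became 1724 with a log2 fold change of at least 1, and leaving out 1 library gave 4984 to 5360. The 2956 higher and 2877 lower genes became 2509 and 3581 with quantile normalisation and 2708 and 3502 with the trend removed. With the replicate block 6231 genes were past the threshold there, 5 of 6 libraries correlated best with the other library of their letter, as a hint from the data and not the design, and the same-letter correlations were 0.0536 to 0.117. That block brought in the immediate early and heat shock list with the preset correlation (camera adjusted p = 0.0031), of which 11 members rose and Hspa1a, Hspa1b, Hspa8 and Hsp90aa1 fell. Without the block, the camera adjusted p of that list was 0.75 with its estimated correlation of 0.69. No named gene or list that was past the threshold reversed its direction in these settings. Over all these settings 52 of 79 named genes and 10 of 18 lists of the first comparison, and 61 of 69 genes and 11 of 18 lists of the second, kept their side of the threshold. Of these, 36 genes and 7 lists, and 60 genes and 10 lists, also kept their direction, and those that changed sign were not past the threshold in any setting. Between CD73+ and CD73– Treg, the block changed the call of no other named gene or list than those given above, and brought in the list members Il1r2, Lgals1, Gpr83, Tnfrsf1b and Myc. The 4 comparisons across the tables and the planned overlap with shared libraries were not run, because the tables were normalised separately. Depth limits genes with few counts, such as Il1rl1 and Cxcr3 in CD73– Treg.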

Other observations

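The tests reported in this part, the splits of libraries included, were all chosen or run after the results they bear on were seen. The comparisons share no library but share the letters, and same-letter libraries of CD73– Treg and Tconv correlated at 0.129 to 0.354 across the tables. Each comparison also set a group with more Nt5e against a group sorted as CD73–. Part of a shared direction may therefore follow from the gates, which was not tested. The comparisons are therefore not fully independent, and neither the values for independent lists nor the Fisher test given here takes this into account. Of the 199 genes higher in CD73+ than in CD73– Treg, 151 were also higher in tdTomato– Treg than in Tconv, where independent lists would share 52.2, and 18 were lower (51.2 for independent lists). Of the 77 lower genes, 50 were also lower (19.8 for independent lists) and 10 were higher. Fisher's exact test across 11167 genes, which are not independent, gave p = 3.3e-49 for the shared higher and p = 4.8e-13 for the shared lower genes. In all, 82.6% of the 276 genes had the same sign in both comparisons, and for the 276 leading genes of the other 9 splits of the same 6 libraries the share was 50.4% to 69.5%, counted in whichever direction gave more, since those splits have none of their own. Those splits mix libraries of both groups on each side, so their shares do not measure what chance gives.

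The 28 genes that passed in opposite directions, named after their values were seen, included 6 histone genes, Il7r, Igfbp4, Zbtb16, Lta and Slamf6. Il7r was 5.48 ± 0.23 (SD, n = 3) in CD73– and 6.21 ± 0.20 in CD73+ newly generated Treg, 7.75 ± 0.05 in tdTomato– Treg and 8.17 ± 0.09 in Tconv. Igfbp4 was 3.99 ± 0.01, 4.54 ± 0.07, 4.80 ± 0.14 and 8.51 ± 0.16 in the same order. These levels come from tables normalised separately and were not tested across them. Among gene families chosen after seeing the data, 12 of 80 cytosolic ribosomal protein genes and 7 of 63 histone genes rose in CD73+ Treg and none fell (adjusted p = 0.0042 and 0.041 with an estimated correlation), and with the replicate block 33 and 13 rose and none fell. In tdTomato– Treg against Tconv, 27 ribosomal protein genes rose and 6 fell (camera adjusted p = 0.16), and 47 histone genes fell and none rose (camera adjusted p = 1.7e-09, and adjusted p = 0.20 with an estimated correlation). With quantile normalisation 25 ribosomal protein and 6 histone genes rose in CD73+ Treg, and no family median among these families and comparisons changed its sign except, in tdTomato– Treg against Tconv, those of the Zfp genes (0.02 and −0.11) and of the mitochondrially encoded genes (0 and 0.03). Of 13 mitochondrially encoded genes none passed in the first comparison (camera adjusted p = 0.41), where mt-Co3 fell with the block, and 2 fell in the second (camera adjusted p = 0.77). Of Zfp zinc finger genes 1 of 307 rose and 4 fell in the first comparison (camera adjusted p = 1.6e-04, and adjusted p = 0.13 with an estimated correlation). With the block 1 rose and 9 fell (camera adjusted p = 2.3e-04). In the second, 51 of 306 rose and 55 fell (camera adjusted p = 0.91).

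The 6 libraries of each comparison allow only 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes in each comparison. The real counts were 276 and 5833, and the highest of the other splits gave 2 and 0 genes. Each of the other splits mixes libraries of both groups on each side. A real difference then adds to the spread within a side and lowers the count, so these counts do not measure what chance gives. Between CD73+ and CD73– Treg, the 3 other splits that part all 3 letter pairs gave 0 genes each, and the 6 that part only 1 pair gave 0 to 2.

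Effector Treg genes higher in CD73+ newly generated Treg could come from a small share of cells with the profile of tdTomato– Treg in the CD73+ gate, a hypothesis that sets levels across separately normalised tables, although the gate on tdTomato+ cells would remove unlabelled Treg. The share each of the 10 called genes would need was lowest for Fgl2, at 3.50% ± 1.03 (SD over 3 letters), which allows at most 5.56% at 2 SD. Ahnak (13.1% ± 1.86) and Ccr8 (36.6% ± 6.59), 2 of the 10, need more than that by over 2 SD, so cells with the mean profile of tdTomato– Treg alone do not account for them. Those Treg were not divided by CD73, so the profile of their CD73+ part was not measured, and an admixture of such cells is not excluded. For the other 8 genes, between 3.50% and 14.4%, an admixture and higher expression in the newly generated cells cannot be told apart. Of these 8, Itgae (7.71% ± 1.09, at least 5.53% at 2 SD) would also lie above the 5.21% that Il1rl1 allows, a bound not used because the CD73– level of Il1rl1 rests on few counts. A trend on length and GC content, as fitted with the longest annotated transcript of each gene, does not account for the rise. The median log2 fold change of the 10 genes was 1.85 before and 1.86 after its removal. A difference in state between CD73+ and CD73– cells, which the design names, stays open as untested.

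Ribosomal protein and histone transcripts are short (median 1100 and 539 nt against 3442 nt over tested genes), and log2 fold changes between CD73+ and CD73– Treg fell with length across 11163 genes (Spearman −0.199) and rose with GC content (0.198), so a technical trend may have raised both families. For ribosomal protein genes, removing the trend in the fit with the replicate block left camera p = 4.9e-04 for the list with an estimated correlation (p = 0.0035 before). The trend, as fitted with the longest annotated transcript of each gene, thus did not remove the whole difference. The family and this choice of fit came after the data were seen, so a technical cause of the rest is not excluded. The median fell from 0.15 to 0.06, and the calls from 33 to 13 with the block and from 12 to 3 without it. For histone genes the limma camera test with an estimated correlation gave p = 0.027 before and p = 0.066 after removal with the block, where the calls went from 13 to 7, and p = 0.048 after removal without it. The median went from 0.37 to 0.16 without the block (SD over genes 0.39 and 0.33), so a trend and a difference in histone transcripts cannot be told apart. Histone reads are also shared between near-identical copies, which was not tested.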
